A study of Mus musculus with 14 samples.

How the data were processed

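RNA of mouse liver tumours was measured by 3′ messenger RNA sequencing in 14 libraries, which are treated as biological replicates from separate animals. Per the labels, 5 libraries came from wild-type tumours (WT), 5 from tumours lacking Cdk18 (CDK18KO) and 4 from tumours lacking both Cdk16 and Cdk18 (DKO). Per the labels' protocols, tumours were started by hydrodynamic injection of plasmids for mouse c-Myc and β-catenin. Cdk16 was deleted once tumours had formed, per the same protocols. Tamoxifen at 75 mg/kg was given on 5 days to animals with a floxed Cdk16 gene and Cre-ERT2, a Cre recombinase switched on by tamoxifen, and to Cre-ERT2 controls. Tissue was taken 10 days later. Animals were followed until a tumour reached 15 mm, distress, or 8 weeks. The labels' protocols give an RNA integrity number of at least 8.0 at extraction and a mean of 8.3 (7.5 to 8.8) at library preparation. Libraries were made from 300.0 ng of RNA with a kit that primes on the poly(A) tail, keeps the strand and adds a 6-base molecular identifier, and single reads of 151 bases were taken.

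The deposited table gives raw counts per gene symbol for 77981 genes and 14 libraries. Per the submitters' processing notes, the authors' tools were FastQC, UMI-tools 1.1.2, STAR 2.7.11a, HTSeq 1.99.2 and DESeq2 1.32.0, and the builds named are mm10 and GRCh38 without a role for either. Whether reads with the same molecular identifier were collapsed before counting, and which annotation was counted, is not given in the sources used here. Counts are therefore treated as reads, and intervals and floors cover counting error only. Genes are named as in the table. Positions come from the GENCODE M21 annotation of GRCm38, which held a position for 93.7% of the tested genes and was used only to say where a gene lies. Columns of single-sample values left unused numbered 0.

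The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors, edgeR's filter on low counts by group, all 14 libraries in 1 fit and Benjamini-Hochberg adjustment over the 13997 genes kept. A gene was called at an adjusted p under 0.05. The tests are two-sided. The genes kept held 99.0% of all counts. Expression is given as CPM, counts scaled to the same library total with TMM factors, and errors are SD over libraries unless SE is written. The SE of a log2 fold change is its size divided by the square root of F. The common biological coefficient of variation was 0.598. The pipeline was tested on simulated data drawn from the real means and library sizes, with 50 genes changed at each fold size. Of genes changed 4-fold, 44% were recovered for CDK18KO against WT among 13658 genes, 26% for DKO against WT among 13619 and 34% for DKO against CDK18KO among 13600. At 16-fold the shares were 82%, 78% and 76%, in the same order. Simulated genes were drawn independently of each other, without the structure that genes share in the real libraries. The shares may therefore overstate what is recovered in the real data.

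For gene groups, 44 lists of pathway, cell-type, sex-biased and sex-linked genes were tested with camera in limma 3.58.1. The lists, the design, the alternatives and the rule for naming genes were written before the data were examined. Camera compares a list's genes with all other genes, here on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the 44 lists. Each list was also tested with an estimated correlation and with fry, a rotation test of whether a list's genes move one way on balance. Members past the gene test are counted over all genes and adjusted over the list alone. Only members kept by the filter on low counts were tested, so some cell-type lists were tested on few of their members. A gene counted well in 1 group alone passes this filter. The naming rule takes Cdk16 and Cdk18 always, then the genes past the threshold, or the 10 genes with the smallest p where fewer than 10 pass, and up to 4 members with the smallest p of each list described. Fewer than 10 passed in each comparison, so the 10 smallest p values set the names. For a group with 1 to 3 counts of a gene, the ratio of counts is given with its exact 95% counting interval, and for a group at 0 a bound from a floor of 3 counts over the group.

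Alternatives, whose effect the closing section gives, were DESeq2 1.42.0, RLE and upper-quartile factors, no filter and a stricter filter, a robust fit, limma voom with sample weights, only the pair of groups compared, the replicate number as a block, log2 Y-linked expression as a covariate, a prior count of 0.5, and each library left out in turn. Leaving out 3 libraries with Y-linked expression above 100.0 CPM, the Y-linked covariate for the lists, the simulated and split-WT overlap of genes, and the hepatocyte list mean as a covariate were added after the data were seen. Comparisons that share the WT libraries were set against 100 simulated pairs of unchanged groups, 50 for the overlap of genes, and against WT split into separate parts. Up to 100 other splits of the libraries per comparison were drawn with a fixed seed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.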

Results

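Messenger RNA was counted by its 3′ ends in 14 mouse liver tumours driven by c-Myc and β-catenin, 5 WT, 5 CDK18KO and 4 DKO. CDK16 and CDK18 are related kinases of the PCTAIRE group. Total counts ran from 1442417 (WT 5) to 6068209 (WT 2). Within groups, libraries differed widely, and the first principal component held 48.8% of the variance. Y-linked genes stood at 202 CPM in WT 3, 778 CPM in WT 5 and 345 CPM in CDK18KO 1, against 32.6 CPM or less in the other libraries and 2.75 CPM or less in every DKO library, so sex is not balanced between the groups.

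Cdk18 counts were low in every library. Its CPM was 2.22, 10.4, 5.24, 1.26 and 4.63 in WT 1 to 5, 1.86, 1.06, 3.42, 2.64 and 0.927 in CDK18KO 1 to 5, and 4.00, 0.563, 1.94 and 1.11 in DKO 1 to 4. The means were 4.76 ± 3.58 (n = 5), 1.98 ± 1.06 (n = 5) and 1.90 ± 1.51 (n = 4), and the groups overlapped. Cdk18 differed from WT by a log2 fold change of -1.24 (SE 0.63, edgeR adjusted p = 0.338) in CDK18KO and -1.26 (SE 0.68, adjusted p = 0.331) in DKO, neither past the threshold, with adjusted p of 0.225 to 0.625 and 0.245 to 0.659 over the alternatives. Without WT 2, the deepest library, these differences were -0.69 and -0.71, and without DKO 1 the second was -1.91. Cdk16 CPM was 47.8, 59.2, 53, 40.0 and 45.5 in WT 1 to 5, 65.8, 36.7, 37.0, 32.7 and 31 in CDK18KO 1 to 5, and 38.9, 18, 48.5 and 17.8 in DKO 1 to 4. Cdk16 differed by -0.67 (SE 0.35, adjusted p = 0.310) between DKO and WT and by -0.27 (SE 0.32, adjusted p = 0.691) between CDK18KO and WT, or by -0.52 in the latter without CDK18KO 1. Between DKO and CDK18KO the difference was -0.39 (SE 0.34, adjusted p = 0.993) for Cdk16 and -0.02 (SE 0.71, adjusted p = 0.999) for Cdk18. For Cdk16 it was -0.15 without CDK18KO 1 and -0.70 without DKO 3, and for Cdk18 -0.67 without DKO 1 and 0.27 without DKO 2. Cdk16 lies at X:20687954-20699880 and Cdk18 at 1:132112237-132139684 in GRCm38. Whether the counted 3′ ends lie inside the deleted parts is not given in the sources used here, so these values check no label.

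**Figure D1:**
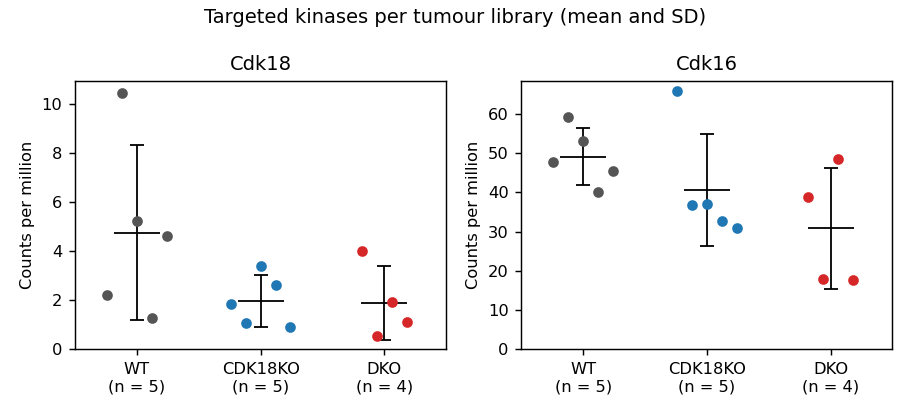
Cdk18 and Cdk16 in CPM for each of the 14 libraries, by group, with the group mean and SD. The groups overlap for both genes.

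The comparison of CDK18KO with WT asks what loss of Cdk18 alone does to the tumour transcriptome. C1rb, one of a pair of mouse complement C1r genes, was at 184 ± 135 CPM in CDK18KO (n = 5) against 1.86 ± 1.63 CPM in WT (n = 5), a log2 fold change of 6.45 (SE 0.88, edgeR adjusted p = 0.046). C1rb was the only 1 of 13997 genes past the threshold. Its call was lost (adjusted p 0.0501 to 0.166) when WT 1, WT 2, WT 3, WT 4, WT 5, CDK18KO 2, CDK18KO 3, CDK18KO 4 or CDK18KO 5 was left out, while its log2 fold change stayed between 5.92 and 7.09. Its neighbours C1ra and C1s1 stood lower: C1ra at 1.23 ± 1.19 against 44.1 ± 40.5 CPM, and C1s1 at 2 counts against 385, a ratio of 145 (40.0 to 1205). WT 2 held 293 of those 385 counts: the ratio was 58.6 (15.8 to 491) without it, 226 without CDK18KO 4 and 244 without CDK18KO 5. C1ra and C1rb are near-identical, so the share of each is uncertain: C1rb held 0 to 10.2% of their summed counts in each WT library and 99.1 to 100% in each knockout library. C1rb, C1ra and C1s1 lie within 6:124512405-124581171.

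**Figure D2:**
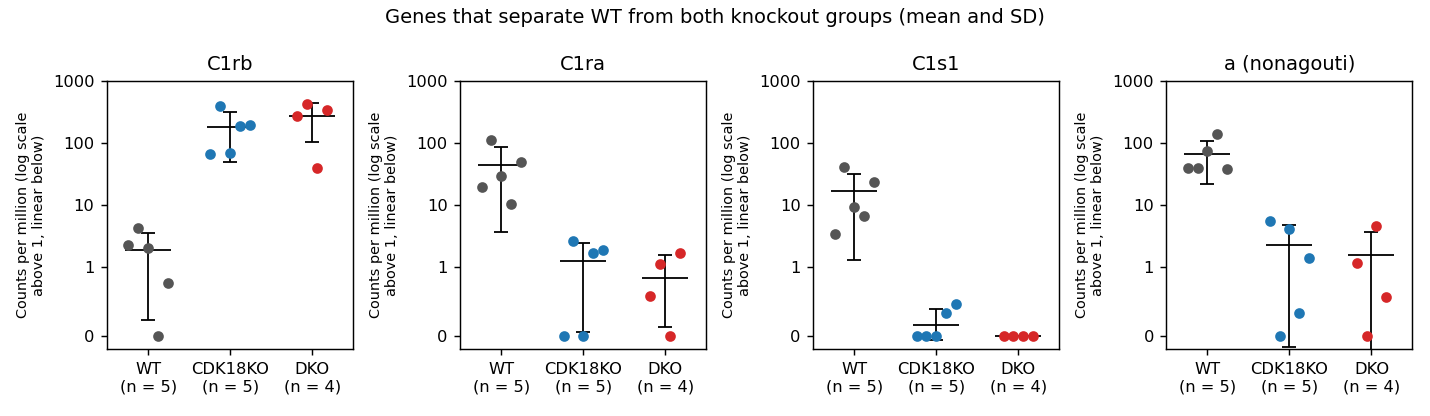
C1rb, C1ra, C1s1 and a (nonagouti) in CPM, on a log scale above 1, for each of the 14 libraries, by group. The WT libraries and the 9 knockout libraries do not overlap for any of the 4 genes.

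At an unadjusted p under 0.05, 2361 genes passed (1618 higher, 743 lower in CDK18KO), where chance would give 699.85. That count was 1459 without CDK18KO 2. DESeq2 called 856 genes (602 higher, 254 lower), and edgeR without CDK18KO 1 called 74 (15 higher, 59 lower). The other 9 of the 10 genes with the smallest p (adjusted p = 0.102 each) were all lower in CDK18KO, with no overlap between the groups. Chl1, a neural adhesion gene, had 1 count against 132, a ratio of 99.7 (17.6 to 3967), or at least 25.3-fold lower with 0 counts without CDK18KO 1. Dlx2 had 3 counts against 120.0, a ratio of 30.2 (10.1 to 149), or 69.03 without CDK18KO 1. Nonagouti (a) fell short of the threshold at 2.27 ± 2.44 against 65.7 ± 43.6 CPM, with a log2 fold change of -4.77 (SE 0.89). Ptgfr differed by -4.90 (SE 0.89), Apod by -4.19 (SE 0.80), the fibroblast gene Thy1 by -2.76 (SE 0.45), C1ra by -5.23 (SE 0.97) and Rps4l by -5.99 (SE 1.13). Rps4l is annotated as a processed pseudogene, so reads shared with its parent gene leave its level uncertain.

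By lists, hepatocyte genes stood higher in CDK18KO and stromal and biliary genes lower. Camera called 18 of 44 lists (11 up, 7 down), 0 of them with an estimated correlation (smallest adjusted p = 0.542), and fry called 1, epithelial to mesenchymal transition (fry adjusted p = 0.0283). Hepatocyte functional genes had a median log2 fold change of 2.54 (SD over members 0.88, camera adjusted p = 2.88e-15, adjusted p = 0.542 with an estimated correlation). Of its 34 members 33 were higher and 16 passed adjusted over the list alone, 0 over all genes by edgeR and 14 by DESeq2. Cps1 was at 585 ± 393 against 46.1 ± 55.3 CPM, a log2 fold change of 3.66 (SE 0.97), and Otc at 112 ± 117 against 7.39 ± 11.7 CPM. Bile acid synthesis and transport had a median of 3.26 (camera adjusted p = 2.54e-09) with 13 of 18 members passing adjusted over the list alone, among them Abcc2 (4.21, SE 1.17), Abcb11 (4.08, SE 1.14) and Nr1h4 (3.25, SE 0.93). In fatty acid oxidation (median 1.84, camera adjusted p = 4.12e-11) 23 of 26 members passed on the list alone, with Acadm at 2.46 (SE 0.64). Fatty acid synthesis (1.38, camera adjusted p = 1.43e-05), cholesterol biosynthesis (1.13, 2.15e-05), xenobiotic response (2.05, 0.000105) and the unfolded protein response (0.58, 5.45e-05) were also called up. The mitochondrial respiratory chain had a median of 0.46 (camera adjusted p = 2.28e-05), which was 0.31 without CDK18KO 2 and 0.30 without CDK18KO 5. With an estimated correlation these lists had adjusted p = 0.542 to 0.699.

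Interferon lists were called up in CDK18KO and tissue lists down, all with adjusted p = 0.542 with an estimated correlation. For interferon γ response and antigen presentation the median was 1.62 (camera adjusted p = 2.80e-09), and 15 of 29 members passed adjusted over the list alone, with Irgm2 at 15.8 ± 9.15 against 2.48 ± 1.76 CPM. For type I interferon response it was 1.68 (5.11e-07), with 13 of 22 members higher and 1 lower on the list alone, and Isg15 at 22.8 ± 14.2 against 4.63 ± 2.36 CPM. Stellate cell and fibroblast markers had a median of -1.59 (camera adjusted p = 3.73e-13), or -2.74 without CDK18KO 1, and 13 of 33 members were lower on the list alone, among them Col6a3 (-2.63, SE 0.56) and Postn (-3.49, SE 0.85). Cholangiocyte markers had a median of -1.63 (0.000101) with 4 of 15 lower, including Krt19 at 0.283 ± 0.278 against 13.1 ± 10.9 CPM and Epcam at 3.47 ± 2.49 against 87.4 ± 40.0 CPM. Epithelial to mesenchymal transition had a median of -1.14 (1.30e-07) with 6 of 28 lower, including Twist1 (-6.73, SE 1.35) and Mmp9 (-4.65, SE 0.89).

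Each of the remaining 5 called lists of this comparison lost its call in 3 to 5 leave-one-out fits. Glycolysis and hypoxia had a median of -0.40 (camera adjusted p = 0.0169), and lost its call without WT 5 (-0.26), CDK18KO 1 (-0.35) or CDK18KO 2 (-0.35). Neutrophil markers had -1.0 (0.0205) and lost it without WT 2 (-0.96), WT 5 (-0.65) or CDK18KO 3 (-0.80), with -1.58 without CDK18KO 5. Heat shock and immediate early genes had -0.40 (0.0286) and lost it without WT 5 (0.01), CDK18KO 2 (-0.48) or CDK18KO 3 (-0.35), with -0.61 without WT 2. Acute phase response had 0.94 (0.0312) and lost it without WT 1 (0.61), WT 3 (0.90), WT 4 (0.77), CDK18KO 1 (0.81) or CDK18KO 5 (0.84), with 0.42 without CDK18KO 2 and 1.98 without WT 2. Oncofetal and liver tumour markers had -0.14 (0.0216), lost without WT 2 (-0.09), CDK18KO 1 (-0.17) or CDK18KO 2 (0.07), and moved to -0.86 without CDK18KO 5, -0.03 without CDK18KO 4, -0.07 without WT 3 and -0.28 without WT 5. With an estimated correlation the 5 lists had adjusted p = 0.666 to 0.699.

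Nuclear pore and repair genes, named in the series title, did not differ by list between CDK18KO and WT. Nuclear pore complex genes had a median of -0.14 (camera adjusted p = 0.663) and nuclear transport factors -0.11 (0.507), with 0 of 30 and 0 of 27 members past the edgeR test adjusted over the list alone and 0 by DESeq2. Pom121 had the smallest p of the nuclear pore list (-0.63, SE 0.27, 0.839 adjusted over the list alone). End joining repair had a median of 0.06 (0.430), excision and mismatch repair -0.01 (0.874), the replication stress checkpoint -0.05 (0.771), and homologous recombination and Fanconi repair -0.03 with a mean of 0.05 (0.788). S phase and DNA replication had -0.26 (0.123), called without WT 5 (-0.38) or CDK18KO 5 (-0.32), but at -0.06 with another library left out. G2 and mitosis had -0.04 (0.911), and Myc-induced ribosome biogenesis -0.07 (0.811). Prim2 alone among S phase genes was lower adjusted over the list alone (-1.64, SE 0.34). For p53 target genes the median was -0.06 and the mean 0.05 (0.811), and for apoptosis genes the median was 0.16 (0.584). Wnt/β-catenin targets and perivenous genes (1.21, 0.223, and 0.62 without CDK18KO 2 or 0.19 without CDK18KO 4), periportal genes (1.06, 0.0664, called without WT 2 at 1.57, WT 5 at 0.87, CDK18KO 2 at 1.18, CDK18KO 3 at 1.23 or CDK18KO 4 at 1.07), erythroid markers (-0.21, 0.546), B and plasma cell markers (-0.29, 0.477), T and NK cell markers (-0.82, 0.338) and macrophage and Kupffer cell markers (0.03, 0.811) were not called either. Only 3 of 36 T and NK cell markers and 5 of 23 B and plasma cell markers had enough counts to be tested.

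The comparison of DKO with WT asks what loss of both kinases does. The labels' protocols, which are the same for all libraries, name Cre-ERT2 controls given tamoxifen. Whether the WT and CDK18KO animals were such controls is not given in the sources used here, so comparisons of DKO do not separate loss of Cdk16 from Cre and tamoxifen. C1rb was again the only 1 of 13997 genes past the threshold, at 269 ± 166 CPM in DKO (n = 4) against 1.86 ± 1.63 in WT (n = 5), a log2 fold change of 7.0 (SE 0.91, edgeR adjusted p = 0.0259). The call was lost without WT 1, WT 2, WT 3, WT 5, DKO 1, DKO 2 or DKO 4 (adjusted p 0.0534 to 0.192), with log2 fold changes of 6.67 to 7.64 over the leave-one-out fits. Unadjusted p under 0.05 took in 2651 genes (1921 higher, 730.0 lower), or 1519 without DKO 2, and DESeq2 called 1033 (875 higher, 158 lower). The other 9 genes with the smallest p had an adjusted p of 0.146 and no overlap between the groups. The acute phase gene Saa2 was at 526 ± 609 against 4.48 ± 4.91 CPM (log2 fold change 6.76, SE 1.1), and has a near-identical copy in Saa1. Ighm, an immunoglobulin heavy chain gene, was at 14.9 ± 14.5 against 0.427 ± 0.258 CPM, the neutrophil granule gene Ltf at 5.39 ± 1.84 against 0.464 ± 0.297 CPM, and Trim30d at 12 ± 11.8 against 0.364 ± 0.233 CPM. The DNA primase gene Prim2 was at 6.03 ± 2.79 against 23.6 ± 3.31 CPM (-1.97, SE 0.38), and Tfap2c at 0.641 ± 0.944 against 33.7 ± 20.8 CPM. C1s1 had 0 counts in DKO and 385 in WT, at least 72.9-fold lower (29.4-fold without WT 2, 47.8-fold without DKO 1), C1ra differed by -5.80 (SE 1.13) and nonagouti (a) by -5.24 (SE 1.01).

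Camera called 30 of 44 lists in DKO against WT (20 up, 10 down), fry 22, and camera with an estimated correlation 0 (smallest adjusted p = 0.192). Hepatocyte functional genes had a median of 3.27 (SD over members 0.69, camera adjusted p = 6.65e-19, adjusted p = 0.236 with an estimated correlation). All 34 members were higher, 32 of them past the test adjusted over the list alone, 0 over all genes by edgeR and 27 by DESeq2. Otc was at 158 ± 166 against 7.39 ± 11.7 CPM and Ugt2b1 at 54.5 ± 62.2 against 2.37 ± 2.84 CPM. Without the 3 libraries with high Y-linked counts the median was 2.86. Bile acid synthesis and transport had a median of 3.57 (4.32e-10) with 16 of 18 members higher on the list alone, periportal genes 2.37 (6.12e-08) with 7 of 19, and fatty acid oxidation 1.63 (1.26e-08) with 19 of 26. Fatty acid synthesis (1.70, 3.47e-07), xenobiotic response (1.82, 3.70e-06), the unfolded protein response (0.64, 3.06e-06) and cholesterol biosynthesis (1.42, 5.93e-06, or 0.85 without DKO 2) were called up too. For Wnt/β-catenin targets and perivenous genes the median was 2.24 (0.00272), with Cyp7a1 at 495 ± 562 against 10.5 ± 15.7 CPM. These lists had adjusted p = 0.236 to 0.365 with an estimated correlation.

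Interferon, acute phase, macrophage, erythroid, neutrophil and B cell lists were also higher in DKO than in WT, while T and NK cell markers (median -0.35, mean 0.06, camera adjusted p = 0.872) and dendritic cell markers (-0.50, 0.726) were not called. Only 3 of 36 T and NK cell markers and 6 of 18 dendritic cell markers had enough counts to be tested, so these lists say little about those cells. The camera adjusted p was 2.50e-13 for interferon γ response and antigen presentation (median 2.39), where 23 of 29 members passed adjusted over the list alone, with H2-K1 at 709 ± 375 against 164 ± 50.3 CPM. Acute phase response had a median of 2.66 (3.39e-11) with 13 of 22 members, type I interferon response 1.81 (6.28e-07) with 10 of 22, and macrophage and Kupffer cell markers 1.05 (6.28e-07) with 7 of 28. Erythroid markers had 1.90 (3.05e-07) with 10 of 12 members, neutrophil markers 1.92 (4.36e-06) with 4 of 11, and B and plasma cell markers 3.26 (5.70e-06) with 4 of 5. The filter on low counts kept only 5 of 23 B and plasma cell markers and 11 of 22 neutrophil markers. Igkc was at 25.7 ± 15.2 against 2.82 ± 2.32 CPM and Ngp at 40.5 ± 13 against 2.51 ± 2.89 CPM. With an estimated correlation adjusted p = 0.192 for B and plasma cell markers and 0.236 for the others.

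Growth, pore and repair lists were lower in DKO than in WT, by less than 1 on the log2 scale. G2 and mitosis genes had a median of -0.65 (camera adjusted p = 5.03e-12, adjusted p = 0.236 with an estimated correlation) and 57 of 58 members lower, of which Ckap2l passed adjusted over the list alone (24.5 ± 4.83 against 50.6 ± 3.70 CPM). Myc-induced ribosome biogenesis had -0.59 (9.69e-09), with all 45 members lower and 0 past the test on the list alone, and S phase and DNA replication -0.61 (1.02e-08), with 5 of 45 past it, including Chaf1a (-1.32, SE 0.35) and Pola2 (-1.15, SE 0.31). Nuclear pore complex genes had -0.39 (0.000701, adjusted p = 0.259 with an estimated correlation), with 29 of 30 lower and 0 past the test over the list alone, all genes or DESeq2. Pom121 (-0.73, SE 0.29), Nup210 (-0.82, SE 0.35), Nup188 (-0.94, SE 0.44) and Nup133 (-0.69, SE 0.33) had the smallest p, each 0.377 adjusted over the list alone. Nuclear transport factors had -0.33 (0.000944), the replication stress checkpoint -0.39 (0.00107, and -0.65 without DKO 3), homologous recombination and Fanconi repair -0.48 (0.00111), and excision and mismatch repair -0.39 (0.00588), with 25 of 27, 21 of 23, 30 of 35 and 25 of 35 members lower and 0 past the edgeR test on each list alone. With an estimated correlation those lists had adjusted p = 0.236 to 0.259. Rad51b went against its list (2.59, SE 0.70). These lists moved with hepatocyte gene expression: within groups their means fell as the hepatocyte mean rose (rho -0.842 to -0.688 over 9 lists, permutation adjusted p of 0.00826 or less). With the hepatocyte mean as a covariate the DKO minus WT difference went from -0.40 (SE 0.17) to 0.0044 (SE 0.15) for nuclear pore genes and from -0.70 (SE 0.22) to -0.14 (SE 0.17) for G2 and mitosis. That covariate itself differs between the groups (8.28 log2 CPM in DKO against 4.70 in WT). It therefore cannot tell a difference in cell content from an effect of genotype on the tumour cells. DKO 3, with a hepatocyte mean of 5.91 log2 CPM, lay inside the WT range for both lists (6.04 and 5.90). End joining repair was not called (-0.32, 0.140), nor were p53 target genes (0.03, 0.957), epithelial to mesenchymal transition (-0.01, 0.200), cholangiocyte markers (0.54, 0.585, called without DKO 2 at 0.78) or stellate cell and fibroblast markers (-0.39, 0.0553, called without WT 1 at -0.43, WT 2 at -0.60, WT 3 at -0.52 or DKO 1 at -0.57). With the Y-linked covariate the stellate list was called the other way (0.58, camera adjusted p = 0.0425).

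Lists of sex-biased and sex-linked genes differed between DKO and WT as well, with adjusted p = 0.236 with an estimated correlation. Female-biased liver genes had a median of 2.94 (camera adjusted p = 0.000331) and male-biased liver genes 2.77 (0.00270). Both were up, as were hepatocyte functional genes (3.27), so these 2 lists do not point to a difference in sex. X inactivation and Y-linked genes had -6.43 (0.0221), with Ddx3y at 0.440 ± 0.542 against 116 ± 183 CPM, and lost the call without WT 1 (-3.53), WT 3 (-1.13), WT 5 (-2.63) or DKO 3 (-5.97). Ribosomal proteins had -0.28 (0.00247, adjusted p = 0.650 with an estimated correlation), lost without WT 3 (-0.16) or DKO 2 (-0.15). The mitochondrial respiratory chain had 0.27 (0.0374, adjusted p = 0.675 with an estimated correlation), lost without WT 1 (0.19), WT 4 (0.19), WT 5 (0.18), DKO 1 (0.13) or DKO 2 (0.17). Immune checkpoint and exhaustion genes had 1.51 (0.0452), lost without WT 1 (1.34), WT 3 (1.41) or DKO 1 (1.69), and 0.86 without DKO 4, with adjusted p = 0.236 with an estimated correlation.

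The comparison of DKO with CDK18KO asks what loss of Cdk16, deleted in formed tumours per the labels' protocols, adds to loss of Cdk18. By edgeR 0 of 13997 genes passed (smallest adjusted p = 0.144), 812 had an unadjusted p under 0.05 (552 higher, 260.0 lower) where chance would give 699.85, and DESeq2 called 84 (80 higher, 4 lower). Without CDK18KO 1 edgeR called 2. The 10 genes with the smallest p were all higher in DKO, with no overlap between the groups, and adjusted p = 0.144 or 0.165. Blood and immune genes among them were Igkc at 25.7 ± 15.2 against 1.36 ± 1.07 CPM (log2 fold change 4.18, SE 0.70), Ngp at 40.5 ± 13 against 1.26 ± 1.28 CPM (5.00, SE 0.96), Hba-a1 at 740.1 ± 519 against 101 ± 34.5 CPM (2.87, SE 0.51), and Ltf with 56 against 3 counts, a ratio of 24.8 (8.06 to 124). Hba-a1 has a near-identical copy in Hba-a2. Krt19, a biliary keratin, was at 19 ± 17.1 against 0.283 ± 0.278 CPM (5.82, SE 1.04), Igf1 at 229 ± 167 against 23.8 ± 18.6 CPM (3.26, SE 0.57), and the clock gene Per2 at 29.5 ± 4.48 against 8.95 ± 3.67 CPM (1.71, SE 0.33). Gpm6a differed by 4.61 (SE 0.78) and Rgcc by 3.62 (SE 0.70). Sema3c differed by 5.61 (SE 1.08), or by 2.71 (adjusted p = 0.281) without DKO 4, which stood at 330.1 CPM against a DKO mean of 91.6 CPM.

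Camera called 29 of 44 lists in DKO against CDK18KO (18 up, 11 down), fry 6, and camera with an estimated correlation 5, all higher in DKO. B and plasma cell markers had a median of 3.55 (camera adjusted p = 5.29e-14, adjusted p = 0.00469 with an estimated correlation), and 5 of 5 tested members passed adjusted over the list alone. The filter on low counts kept only 5 of the 23 members of this list, 11 of 22 neutrophil, 12 of 18 erythroid and 5 of 19 immune checkpoint genes. Members such as Ltf can pass that filter because DKO is high, so the shares of tested members passing partly follow from the filter. Neutrophil markers had 2.92 (3.21e-20, and 0.0407 with an estimated correlation) with 8 of 11, including S100a9 at 195 ± 19.5 against 12.4 ± 13.8 CPM. Erythroid markers had 2.77 (1.63e-15, and 0.0465) with 10 of 12, or 1.76 without DKO 4, including Hbb-bt (2.22, SE 0.55). Cholangiocyte markers had 1.81 (5.67e-10, and 0.0465) with 5 of 15, including Krt7 (4.97, SE 1.12). Immune checkpoint and exhaustion genes had 1.5 (0.000358, and 0.0407) with Vsir (1.61, SE 0.44) as the 1 of 5 passing, or 0.79 without DKO 4. DESeq2 called 4 of 5 B and plasma cell markers, 5 of 11 neutrophil markers and 6 of 12 erythroid markers. T and NK cell markers (median 1.34, camera adjusted p = 0.152, called without DKO 3 at 1.70 or without the 3 high-Y libraries at 1.71, and 0.47 without DKO 1) and dendritic cell markers (-0.05, mean 0.05, 0.516) were not called. These 2 lists were tested on only 3 of 36 and 6 of 18 members.

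Tissue and stress lists were called up in DKO against CDK18KO by camera but not with an estimated correlation (adjusted p = 0.0870 to 0.218). Stellate cell and fibroblast markers had a median of 1.23 (6.68e-15), or 2.01 without CDK18KO 1, with Thy1 at 2.31 (SE 0.47). Epithelial to mesenchymal transition had 0.84 (1.09e-08), or 1.33 without CDK18KO 1, and macrophage and Kupffer cell markers 0.96 (2.86e-11). Acute phase response had 1.61 (8.15e-12), or 0.92 without DKO 1. Endothelial cell markers had 0.87 (2.31e-06), or 1.4 without CDK18KO 2 and 0.53 without DKO 1, and periportal genes 0.93 (3.41e-06), or 1.83 without CDK18KO 5 and 0.54 without DKO 1. Heat shock and immediate early genes had 0.43 (7.13e-05), or 0.74 without CDK18KO 4.

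Growth, pore and repair lists were lower in DKO than in CDK18KO, again by less than 1 and with calls lost with an estimated correlation. G2 and mitosis had a median of -0.63 (camera adjusted p = 1.06e-22, adjusted p = 0.0870 with an estimated correlation) with 57 of 58 lower and Ckap2l (-1.13, SE 0.23) past the test adjusted over the list alone. Myc-induced ribosome biogenesis had -0.52 (2.33e-15, and 0.128 with an estimated correlation) with all 45 lower, and S phase and DNA replication -0.44 (8.64e-10, and 0.215), or -0.68 without DKO 3. Homologous recombination and Fanconi repair had -0.50 (3.27e-07, and 0.128) with Brip1 at -0.97 (SE 0.28), and excision and mismatch repair -0.29 (0.000216, and 0.128). Nuclear pore complex genes had -0.30 (4.46e-05, and 0.218) with 25 of 30 lower, or -0.19 without CDK18KO 5, -0.19 without DKO 2 and -0.51 without DKO 3. Nuclear transport factors had -0.27 (0.000333, and 0.218). The replication stress checkpoint had -0.35 (3.59e-05, and 0.152), or -0.22 without DKO 1, -0.23 without DKO 2 and -0.53 without DKO 3, and end joining repair -0.29 (0.000382, and 0.128), or -0.10 without DKO 1 and -0.59 without DKO 3. With the hepatocyte mean as a covariate the DKO minus CDK18KO difference went from -0.30 (SE 0.17) to -0.22 (SE 0.11) for nuclear pore genes and from -0.65 (SE 0.22) to -0.54 (SE 0.13) for G2 and mitosis. Nuclear pore means were 5.60 in CDK18KO 2 and 5.64 in CDK18KO 4, close to DKO 4 (5.63), and 6.04 in DKO 3. In each of these pore, transport and repair lists 0 members passed the edgeR test on the list alone and DESeq2 called 0.

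Hepatocyte and metabolic lists had medians within 1 of 0 between DKO and CDK18KO. Hepatocyte functional genes had a median of 0.59 (camera adjusted p = 0.0337, adjusted p = 0.749 with an estimated correlation), lost without CDK18KO 1 (0.33), CDK18KO 3 (0.34), DKO 1 (0.51) or DKO 2 (-0.04), with 1.22 without CDK18KO 2 and 0.97 without DKO 3. Fatty acid oxidation was not called (-0.09, 0.350), but was without CDK18KO 1 (-0.30), CDK18KO 3 (-0.26) or DKO 2 (-0.59). Its median turned as far as 0.34, not called, with another library left out. Bile acid synthesis and transport was not called (0.28, 0.350), but was without CDK18KO 2 (0.91), CDK18KO 4 (0.77) or DKO 3 (0.62). The median of the bile acid list turned as far as -0.26, not called, with another library left out. Type I interferon response (-0.01 with a mean of 0.07, 0.917) was called only without DKO 3 (0.35). Interferon γ response and antigen presentation had 0.47 (0.00421, and 0.568 with an estimated correlation), lost without CDK18KO 1 (0.36), CDK18KO 3 (0.37), DKO 1 (0.31) or DKO 2 (0.12), with 0.89 without CDK18KO 2 and 0.83 without DKO 3.

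Each of the remaining 6 calls between DKO and CDK18KO was lost in 1 to 4 leave-one-out fits, with adjusted p = 0.237 to 0.628 with an estimated correlation. Female-biased liver genes had a median of 0.64 (camera adjusted p = 0.00497), lost without DKO 1 (0.55) or DKO 2 (0.31), with 1.30 without CDK18KO 2 and 1.12 without DKO 4. Male-biased liver genes had 0.76 (0.0362), lost without CDK18KO 3 (0.48), CDK18KO 5 (0.60), DKO 1 (0.57) or DKO 2 (0.54), with 1.33 without CDK18KO 1. X inactivation and Y-linked genes had -4.65 and were not called (0.0744), but were without CDK18KO 4 (-4.96). Wnt/β-catenin targets and perivenous genes had 0.30 (0.0115), lost without CDK18KO 5 (0.16) or DKO 2 (0.08), with 1.07 without CDK18KO 2 and 0.47 without DKO 4. The respiratory chain had -0.23 (0.00438), lost without CDK18KO 2 (-0.16), CDK18KO 5 (-0.08) or DKO 3 (-0.08), with -0.36 without CDK18KO 3. Ribosomal proteins had -0.17 (0.000216), lost without DKO 2 (-0.05), with -0.26 without CDK18KO 2, -0.11 without CDK18KO 3 and -0.30 without DKO 4. Oncofetal markers were called up (0.0192) with a median of -0.15 and a mean of 0.22, and lost the call without CDK18KO 1 (-0.33), CDK18KO 2 (-0.31), DKO 1 (-0.23) or DKO 4 (-0.36), with 0.54 without CDK18KO 5. Their median was -0.30 without CDK18KO 3, -0.35 without CDK18KO 4, -0.06 without DKO 2 and -0.08 without DKO 3.

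**Figure D3:**
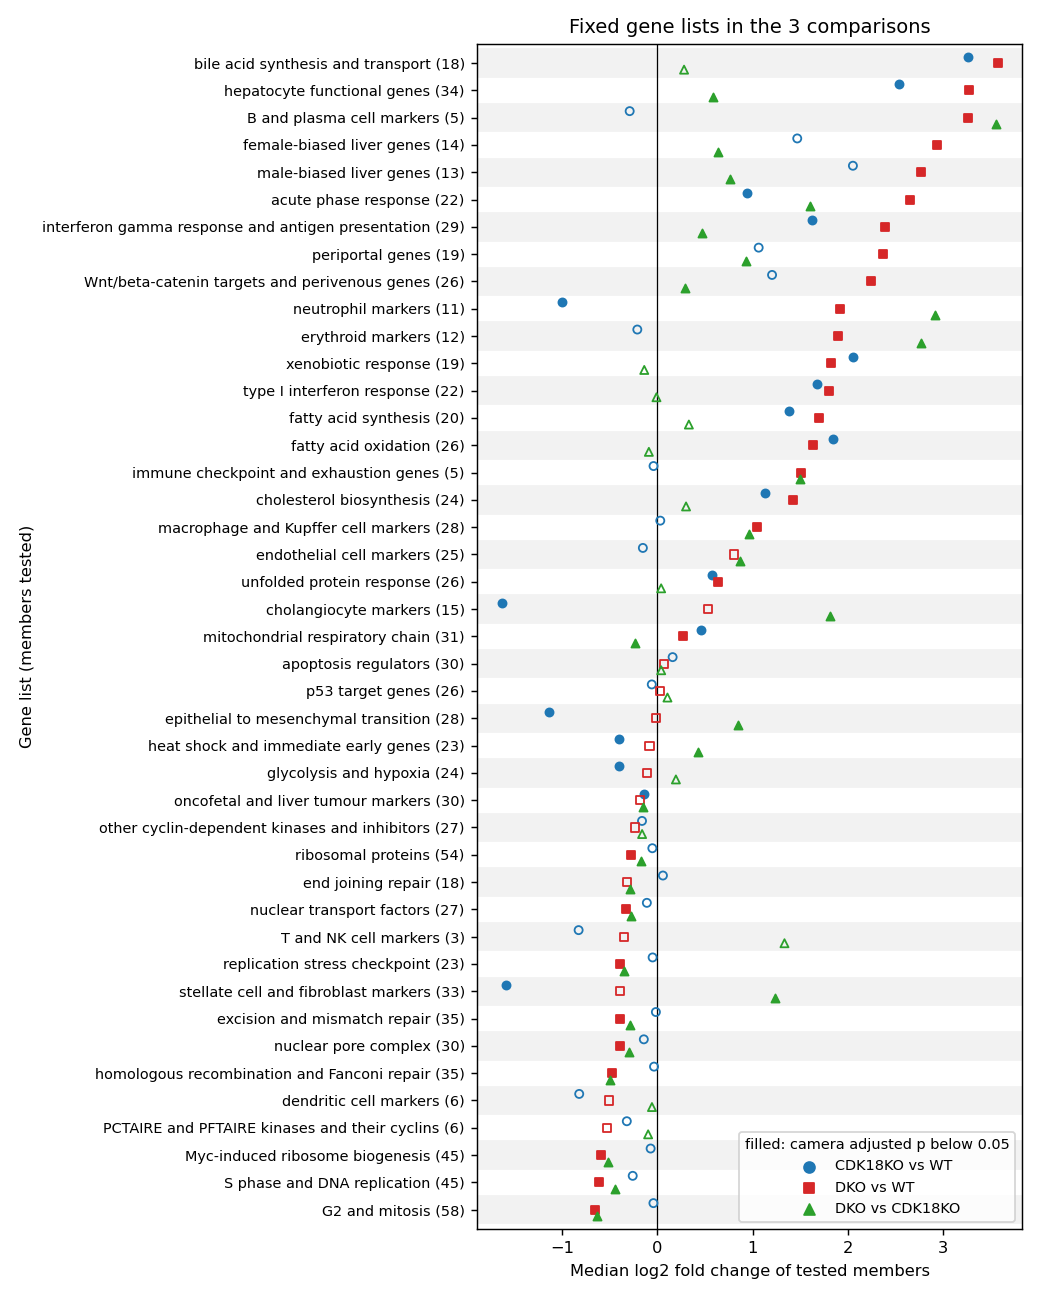
Median log2 fold change of the gene lists in the 3 comparisons, leaving off X inactivation and Y-linked genes, with filled points for lists past camera's adjusted threshold at the preset correlation. Hepatocyte, bile acid and fatty acid lists sit right of 0 in both comparisons with WT, and erythroid, neutrophil and B and plasma cell lists in both comparisons of DKO.

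**Figure D4:**
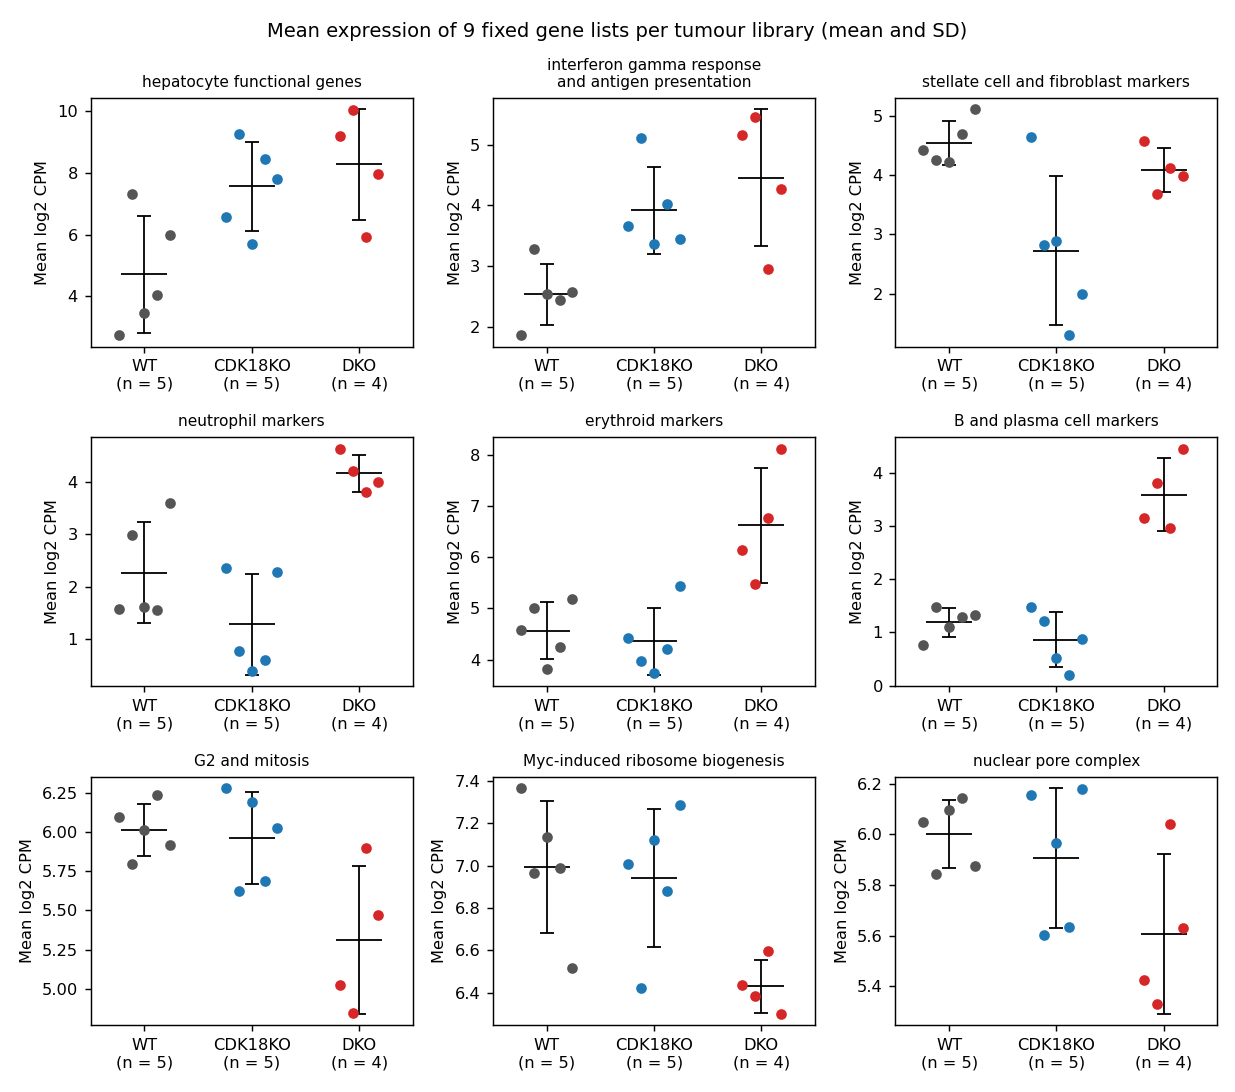
Mean log2 CPM of the members of 9 gene lists in each of the 14 libraries, by group, with the group mean and SD. Neutrophil and B and plasma cell lists are highest in DKO, and hepatocyte genes spread widely within every group.

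Both comparisons with WT share its libraries, which alone makes them alike. Their log2 fold changes correlated across genes at 0.818, against 0.470 (0.449 to 0.495) for simulated unchanged groups sharing WT, and at a mean of 0.669 (0.519 to 0.773) over 20.0 splits giving each comparison its own WT libraries. Genes are not independent replicates. The simulated groups, here and below, drew each gene independently, without the structure that genes share in the real libraries. Simulated values may therefore be too low and their ranges too narrow, so the excess over them does not measure an effect of genotype. The covariance was 0.963 against a simulated 0.178, a difference of 0.785. The same sign was shared by 78.7% of genes, against 65.6% simulated and 69.2% with WT split. Of genes at unadjusted p under 0.05, 1158 were higher in both, against 83 (63 to 102) for simulated unchanged groups sharing WT in 50 draws, and 327 (114 to 582) with WT split. For genes lower in both the numbers were 197, 45.1 (27 to 61) and 63.3 (43 to 78). Lists of the observed sizes drawn independently would share 222.1 and 38.8, and with WT split 76.7 and 19.7. Past the adjusted threshold C1rb was the 1 gene in both. For 83 genes (0.593% of those tested, against 0.0999% for independent libraries) the 5 WT libraries did not overlap the 9 knockout libraries.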

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

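In 14 of 216 checks of 1 library against the rest of its group a library stood apart, where 10.8 would be expected by chance. Leaving out the 3 high-Y libraries, CDK18KO 1 among them, and the Y-linked covariate for lists were chosen after the data were seen. For genes and lists alike, all values below are log2 CPM, as list means where a list is named, except the CPM of Cdk16. Cdk16 was at 65.8 CPM in CDK18KO 1 and at 31 to 37.0 in the other CDK18KO libraries. PCTAIRE and PFTAIRE kinases and their cyclins averaged 4.33 in WT 1 and 4.76 to 4.89 in the other WT libraries. Prim2 was at 4.91 in WT 3 (others 4.47 to 4.57) and at 2.30 in CDK18KO 2 (others 3.05 to 3.24). Excision and mismatch repair genes averaged 4.72 in DKO 3 and 4.36 to 4.39 in the rest of DKO.

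CDK18KO 2 had glycolysis and hypoxia genes at 4.37 (others 5.70 to 5.82) and female-biased liver genes at 4.96 (others 2.56 to 2.93). CDK18KO 3 had acute phase genes at 3.30 (others 4.64 to 5.14). WT 2 had type I interferon genes at 2.92 (others 2.22 to 2.29) and male-biased liver genes at 2.67 (others 1.22 to 1.57). CDK18KO 1 had X inactivation and Y-linked genes at 5.53 (others 1.70 to 2.25) and Chl1 at -0.023 (others -0.57). DKO 4 had Ighm at 5.22 (others 2.91 to 3.19) and Sema3c at 8.37 (others 3.51 to 3.96).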

How the results depend on the processing

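Leaving out the 3 libraries with high Y-linked counts, and the Y-linked covariate for the lists, were chosen after the data were seen. Genes called in CDK18KO against WT, DKO against WT and DKO against CDK18KO (1, 1 and 0) were the same with RLE or upper-quartile factors or the stricter filter. They were 173, 252 and 42 with no filter, 297, 438 and 0 with the replicate number as a block, 856, 1033 and 84 with DESeq2, 0, 1 and 0 with the robust fit, and 0 in all 3 with the Y-linked covariate, only 2 groups, voom weights or the high-Y libraries left out. Leaving out 1 library gave 0 to 74, 0 to 1 and 0 to 2. Replicate numbers do not pair the libraries: correlations within the 13 pairs ran from -0.232 to 0.654, so the block calls have no basis in the samples. C1rb was called in 7 of 21 alternatives for CDK18KO (adjusted p 7.07e-14 to 0.192) and 9 of 20.0 for DKO (7.00e-15 to 0.363), with log2 fold changes of 5.92 to 7.09 and 6.39 to 7.64. Lists called (18, 30 and 29) were 0, 0 and 5 with an estimated correlation, 1, 22 and 6 with fry, 15, 28 and 29 with the Y-linked covariate, and 15 to 19, 28 to 32 and 24 to 35 with 1 library left out. The direction of camera's test turned in 3 cases: stellate markers in DKO against WT with the Y-linked covariate (0.58, adjusted p = 0.0425), and in DKO against CDK18KO without DKO 2 hepatocyte genes (-0.043 there, 1.22 without CDK18KO 2) and cholesterol biosynthesis (-0.21 there, 0.59 without DKO 3). In 8 further cases a list called in either fit changed the sign of its median alone: in CDK18KO against WT heat shock genes without WT 5 (0.0089) and oncofetal markers without CDK18KO 2 (0.069), and in DKO against CDK18KO oncofetal markers with the block (0.70) or without CDK18KO 5 (0.54), xenobiotic response without CDK18KO 2 (0.40), CDK18KO 4 (0.45) or DKO 3 (0.15), and type I interferon response without DKO 3 (0.35). Counting lists called in neither fit, 103 medians changed sign. The correlation of both comparisons with WT was 0.818 with RLE and 0.788 with DESeq2.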

Other observations

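The list of Wnt target and perivenous genes holds parts that move opposite ways in these tumours. Over the 14 libraries, the mean of 8 direct feedback genes (Axin2, Nkd1, Sp5, Notum, Rnf43, Znrf3, Tcf7, Lef1) fell as the hepatocyte list mean rose (Spearman rho -0.640, two-sided permutation p = 0.0162, 0.0487 adjusted over 6 relations; Pearson r -0.621, and -0.666 without the 2 farthest libraries). Within groups rho was -0.468 (permutation p = 0.0946). Perivenous genes such as Glul and Cyp2e1 rose with the hepatocyte list (rho 0.974, permutation p = 1e-05, the smallest these permutations can give). In CPM, Nkd1 averaged 324 ± 40.8 in WT (n = 5), 182 ± 242 in CDK18KO (n = 5) and 168 ± 168 in DKO (n = 4), and Tcf7 averaged 89.7 ± 14.0, 44.9 ± 43.4 and 39.6 ± 19.4. Not every feedback gene averaged far lower in the knockouts: Znrf3 averaged 108 ± 52.2, 101 ± 39.1 and 114 ± 63.9, and Rnf43 averaged 68.5 ± 21.3, 48.2 ± 17.6 and 60.1 ± 18.3. Cyp2e1 averaged 45.7 ± 56.4, 505 ± 705 and 912 ± 1134.

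Xist and Y-linked genes were both counted in several libraries, with Xist at 32 CPM in WT 3, 111 in WT 5 and 64.3 in CDK18KO 1, and at 441 CPM or more elsewhere. Alb averaged 387 ± 465 CPM in WT, 618 ± 492 in CDK18KO and 2089 ± 1404 in DKO, and H19 averaged 509 ± 633, 3099 ± 1705 and 1571 ± 1113. S100a8 averaged 56.9 ± 58.3, 18.6 ± 20.9 and 189 ± 53.3 CPM.

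Chosen after results were seen were the tests of reads shared between C1ra and C1rb, of erythroid content, of tumour share and of normal hepatocytes, with the relation to oncofetal markers. The real grouping was set against other splits of the same libraries, 100 per comparison with the real one included. For called genes, 1 of 100 splits reached the count in CDK18KO against WT (1, highest other 0) and 3 of 100 in DKO against WT (1, highest other 911), but that count is C1rb alone. Its call is lost in 9 of 10 and 7 of 9 leave-one-out fits, though its log2 fold change stayed at 5.92 to 7.09 and 6.67 to 7.64. The number of called genes therefore does not exclude chance. For genes at unadjusted p under 0.05 in CDK18KO against WT, 4 of 100 splits were as high (2361, highest other 3118). That share is under 0.05 only before any adjustment over the 9 counts tested in this way, so chance is not excluded for this count. The count itself ran from 1459 (without CDK18KO 2) to 3276 (without CDK18KO 1) with 1 library left out. Chance cannot be excluded for the number of lists (18, highest other 26, 28 of 100 splits). For DKO against WT it cannot be excluded for unadjusted genes (2651, highest other 3862, 7 of 100) or lists (30, highest other 31, 5 of 100). For DKO against CDK18KO it cannot be excluded for called genes (0, highest other 1145, 100 of 100 splits), unadjusted genes (812, highest other 4233, 36 of 100) or lists (29, highest other 36, 9 of 100). Splits calling 911, 1115 and 1145 genes point to a structure of the samples other than genotype. The 5 splits of DKO and CDK18KO libraries calling 518 genes or more all put CDK18KO 1, CDK18KO 3 and DKO 3 on the side opposite CDK18KO 2 and CDK18KO 4. CDK18KO 1 (-48.6), CDK18KO 3 (-38.4) and DKO 3 (-63.8) were the only knockout libraries on the WT side of the first principal component. Their hepatocyte list means also lay inside the WT range. The split calling 911 genes put WT 2, the highest of WT on that component (-18.6), with DKO 1, DKO 2 and DKO 4.

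C1rb, C1ra, C1s1 and nonagouti separate every WT library from every knockout library. Linked strain or passenger variants are possibly the source: 6 pairs among the 50 best separating genes lie within 1 Mb, a number reached in 13 of 100 splits (median of the others 2, highest 21), which leaves it open. Reads shared alike between the near-identical C1ra and C1rb in all libraries would give similar shares everywhere. C1rb held 0 to 10.2% of their summed counts in WT libraries and 99.1 to 100% in knockout libraries, which argues against such sharing alone. Reads moved by linked variants could account for C1rb's call and stay open. The sum of C1ra and C1rb differed by 2.33 on the log2 scale (exact permutation p = 0.00899), but by 0.21 (SE 0.51, 95% interval -0.91 to 1.33) with the hepatocyte list mean as a covariate, which was added after the values were seen. A like sum does not tell moved reads from a true switch between the 2 genes. Without the covariate, as first worded, the test would have argued against read sharing. Sex alone is unlikely for C1rb, C1ra, C1s1 and nonagouti. WT 1, WT 2 and WT 4 lay apart from the knockouts with Y-linked counts below 100 CPM. High-Y CDK18KO 1 lay with the other knockouts (C1rb 66.8 CPM). Without the 3 high-Y libraries the 10 smallest-p genes of each WT comparison kept 99.7% of their median size (5.24 to 5.22). Those genes were picked for small p in these data, so that test could hardly fail. For other genes sex stays open. With the Y-linked covariate, genes at unadjusted p under 0.05 fell from 2361 to 1097 and from 2651 to 1207.

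Erythroid, neutrophil and B and plasma cell lists were higher in DKO than in CDK18KO, macrophage markers lost their call with an estimated correlation (adjusted p = 0.128), and T and NK markers (called without the 3 high-Y libraries, 1.71, adjusted p = 0.00423) and dendritic markers were not called. With 3 of 36 T and NK markers and 6 of 18 dendritic markers tested, those cells were largely unmeasured. A single source of erythroid and neutrophil RNA, such as retained blood or bleeding, could account for part: their deviations from group means correlated at r 0.447 (permutation p = 0.109, rho 0.495), which leaves it open. With the erythroid list mean as a covariate the neutrophil and B and plasma lists lost their calls (adjusted p = 0.242 and 0.116 with an estimated correlation), which as first worded would have counted for erythroid content alone. The list-mean difference went from 2.88 (SE 0.56) to 1.79 (SE 0.86) for neutrophil markers, and from 2.74 (SE 0.34) to 2.19 (SE 0.54) for B and plasma markers. The wider SE is left by a covariate that itself differs between the groups. For B and plasma markers most of the difference stayed. There, however, the list mean took the place of the lost call after the values were seen, and only 5 of 23 members were tested. Erythroid content alone therefore stays open for both lists. A lower tumour share raising all other cell types alike would move the neutrophil and endothelial lists by the same amount. Neutrophil minus endothelial list means differed by 2.0 between DKO and CDK18KO (exact permutation p = 0.0238). This pair of lists was chosen after their values were seen, and neutrophil members can pass the filter on low counts because DKO is high. The difference therefore cannot decide the question. Macrophage, endothelial and stellate markers were also called up by camera, so a lower tumour share stays open.

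Hepatocyte genes were higher in both knockout groups than in WT by camera, though not with an estimated correlation (adjusted p = 0.542 and 0.236), and CDK18KO 1 (list mean 6.58 log2 CPM), CDK18KO 3 (5.70) and DKO 3 (5.91) lay inside the WT range (2.72 to 7.33). Library depth is unlikely to be the cause (rho -0.0593 with total counts, permutation p = 0.845). Sex alone is unlikely too, since DKO against WT kept 87.4% of the median (3.27 to 2.86) without the 3 high-Y libraries. A part played by sex stays open, as every DKO library was low in Y-linked counts. With the Y-linked covariate, related lists in DKO against WT had lower medians but stayed called. Bile acid synthesis and transport went from 3.57 to 2.57, fatty acid oxidation from 1.63 to 1.34, fatty acid synthesis from 1.70 to 1.30 and cholesterol biosynthesis from 1.42 to 0.79. Normal liver mixed into the tumour samples is possible and left open by the tests made. The fetal and tumour genes Afp, H19 and Gpc3 (Igf2 was not among the tested genes) had rho 0.552 with the hepatocyte list (permutation p = 0.0438, 0.0877 adjusted; within groups rho 0.675, permutation p = 0.00978), while the 30-gene oncofetal list had rho -0.0637 (permutation p = 0.833) and the Wnt feedback genes -0.640.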
